A study of Glyptonotus antarcticus with 18 samples.

How the data were processed

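RNA was measured by sequencing in 18 libraries of juvenile Glyptonotus antarcticus, a giant isopod crustacean of the Antarctic sea floor. Each library came from a pool of 3 whole juveniles preserved in RNAlater. Per the labels, total RNA was extracted with a commercial kit and libraries were made with a stranded mRNA kit. Group and replicate were taken from the sample titles. There were 6 groups of 3 libraries: controls taken at 1 h and at 24 h, and animals held at 5 °C and taken at 1 h, 6 h, 12 h and 24 h. The labels do not give the temperature of the controls, and there was no control group at 6 h or 12 h. The labels describe each library as a pool of its own but do not say how the pools were housed, so p-values measure the spread between these pools.

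Per the submitters' processing notes, reads were processed with Trimmomatic and Salmon; versions and settings are not given in the sources used here. The deposited files list, per gene, a length, an effective length, a TPM value and an estimated count, per the file headers. The estimated counts deposited by the authors need not be whole numbers and are not normalised, and their sum differs between libraries. The TPM values deposited by the authors are scaled by salmon to transcript length and to one fixed total per library, and no comparison uses them. The deposited length is in bases and, for a gene with several assembled transcripts, differs between libraries, since salmon weights the transcripts by their abundance. The effective length is shorter than the length by the mean fragment length, per the file headers and the values. Gene identifiers are those of a Trinity assembly, in which reads are joined into transcripts with no genome. One gene of the animal can be split over several identifiers, and related genes can share reads. The files do not pair these identifiers with gene names and no reference was used here, so no list of genes by function was run and genes are reported by identifier.

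Each file listed the same 175629 genes. Estimated counts were rounded to whole numbers. Library totals ran from 22862654 to 37770184 reads. Genes were kept by edgeR's filterByExpr on the 6 groups with a minimum count of 10, which left 28525 genes. The genes not kept held between 0.313% and 1.64% of the reads of a library. TMM factors scaled the libraries; with no such composition factors the median log2 change over all genes moved by 0.29 at 1 h, 0.13 at 6 h, 0.17 at 12 h, 0.03 at 24 h, 0.18 between the control groups, 0.16 over all times and -0.26 for the difference between the 24 h and the 1 h effect, so changes are relative to the TMM scale. All named genes that passed kept their direction on both scales. edgeR 4.0.16 (R 4.3.3) fitted group means to all 18 libraries with one shared estimate of the spread (estimateDisp, glmQLFit with legacy=TRUE, glmQLFTest). The common biological coefficient of variation was 0.338. P-values were adjusted by the Benjamini-Hochberg method over the 28525 genes, and genes with an adjusted p under 0.05 are called changed. All adjusted p-values in the text are from this edgeR quasi-likelihood test unless another tool is named. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Levels are CPM with TMM factors, as mean ± SD over 3 libraries.

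The contrasts were 5 °C 1 h against Control 1 h, 5 °C 24 h against Control 24 h, 5 °C 6 h and 12 h each against the mean of both control groups, Control 24 h against Control 1 h, the difference between the 24 h and the 1 h effect, any difference among the 4 times at 5 °C, and the mean of the 4 groups at 5 °C against the mean of both control groups. The difference between whole profiles was tested by an exact permutation test of the PERMANOVA pseudo-F between libraries at 5 °C and controls, over all 18564 ways to choose 6 of 18 libraries, on Euclidean distances of log2 CPM with a prior count of 2. Named genes followed a rule set before the data were examined: per comparison, at most 2 that rose and 2 that fell, those with the smallest p among genes with an adjusted p under 0.05, a mean of 10 or more counts and no overlap between the libraries compared; where no gene qualified, the gene with the smallest p in each direction is given as a value that did not pass. Contrasts, tests, the rule and a list of alternatives were fixed at that point; alternatives chosen after seeing the data are named as such. Folds against groups with 0 counts are lower bounds against a floor of 3 counts summed over the group, and ratios with 1 to 3 counts have exact 95% binomial intervals. Both cover counting error only.

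The scripts were tested on simulated data. Counts were drawn for the 28525 genes from the real means, spread and library sizes, with 200 genes changed. At 4-fold, edgeR recovered 36% of the changed genes at 1 h, 70% at 6 h, 62% at 12 h, 47% at 24 h and 47% between the control groups; at 2-fold it recovered 5%, 16%, 8%, 4% and 3%. Unchanged genes called numbered 0 to 6 per comparison. The simulation used a single spread per gene for all groups, and changed genes dropped by the filter counted as missed. The real comparisons called 23 to 6722 genes, and the cut-off on the unadjusted p depends on that number. These shares are therefore not the sensitivity of the real tests. Libraries of one group were compared for duplicates: the chi-square per degree of freedom between same-group pairs was 6.74 or more, so none agreed within counting noise. Alternatives were other scalings, other filters, other tests (DESeq2 1.42.0, limma-voom with limma 3.58.1), a replicate block, other control references and leaving out each library in turn. For each count of genes, other groupings of the same libraries were also counted, all 10 for 3 against 3 and 100 drawn at random otherwise. Shifts of the deposited length were tested with limma on log2 values in 7740 genes that had at least 10 reads in every library and a range over 0.05; on simulated data with shifts of 0.3 in 200 genes it recovered 74% at 12 h against both controls and 66% at 12 h against 6 h, with 8 unshifted genes called in each.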

Results

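The study asked how far juveniles of the Antarctic isopod Glyptonotus antarcticus change their transcripts under acute thermal stress, here 5 °C for 1 h, 6 h, 12 h or 24 h, with controls at 1 h and 24 h. Each group had 3 libraries, each from a pool of 3 whole animals. The 18 libraries held 22862654 to 37770184 estimated reads, and between 20815 and 25837 genes had 10 or more reads in a library. One gene, TRINITY_DN50022_c14_g5, singled out after its values were seen, took from 14.6% of the reads in Control 1 h replicate 1 to 34.5% in Control 24 h replicate 2. Its level did not pass the test in any comparison; at 12 h against both controls its log2 fold change was -0.33 ± 0.21 (SE), with an edgeR adjusted p of 0.253. The 100 most abundant genes together took 45.3% to 57.0% of the reads of a library.

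The first question was how far the transcriptome of animals at 5 °C lay from that of controls. Libraries at 5 °C and control libraries differed as whole profiles: the pseudo-F was 3.59, with an exact permutation p of 0.000485 (9 of 18564 groupings as large). The groupings exchanged single libraries, while libraries of the same group resemble each other (52.8% of the squared distances lay between the 6 groups). This p treats the libraries of a group as independent and does not measure the spread between groups. The division into libraries at 5 °C and controls, which also differ in the times sampled, accounted for 18.3% of the squared distances (14.8% without Control 1 h replicate 1). The first principal component, with 32.7% of the variance, set Control 1 h replicate 1 apart from the other libraries, and the second, with 18.2%, set the 5 °C libraries of 1 h and 12 h apart from the rest.

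**Figure D1:**
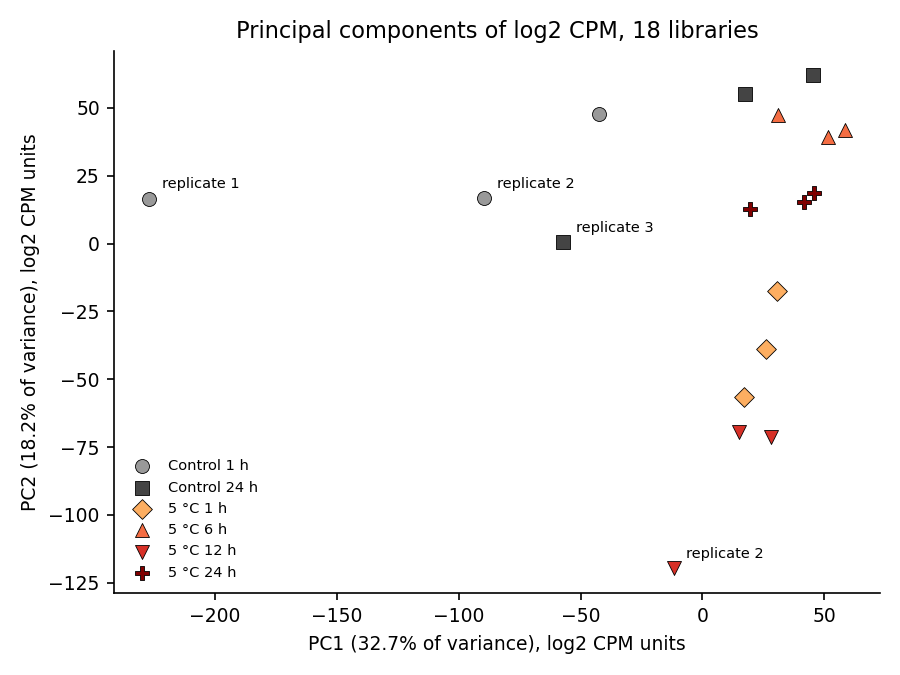
Principal components of log2 CPM over 28525 genes, one point per library, coloured by group; both axes are in log2 CPM units, and PC1 carries 32.7% and PC2 18.2% of the variance. Control 1 h replicate 1 lies at -227 on PC1, and the 6 libraries of 5 °C 1 h and 12 h all lie below 0 on PC2.

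Averaged over the 4 times, TRINITY_DN46346_c0_g1 and TRINITY_DN54770_c6_g1 were higher at 5 °C, and TRINITY_DN54611_c1_g1 and TRINITY_DN52172_c6_g1 were lower. TRINITY_DN46346_c0_g1 rose 3.40-fold (log2 1.76 ± 0.15 SE, adjusted p = 4.7e-05), from 0.813 ± 0.090 CPM in Control 1 h and 1.56 ± 0.42 in Control 24 h to group means between 2.90 and 5.45 CPM at 5 °C (SD, n = 3 each). TRINITY_DN54770_c6_g1 rose 3.03-fold (log2 1.60 ± 0.15 SE, adjusted p = 6.07e-05) and reached 68.0 ± 9.9 CPM at 12 h, against 10.4 ± 2.1 in Control 1 h and 24.3 ± 4.7 in Control 24 h. TRINITY_DN54611_c1_g1 fell 7.30-fold and TRINITY_DN52172_c6_g1 fell 8.15-fold, with adjusted p of 6.07e-05 and 7.19e-05. By the rule for naming them, all 4 genes separated the 12 libraries at 5 °C from the 6 controls without overlap. They passed the test whichever library was left out. In all, 6776 of 28525 genes changed, 2479 higher and 4297 lower. Among genes with a mean of 10 or more counts, 95 were higher and 70 lower in every 5 °C library than in every control library. This is 0.714% of the 23116 genes. It would be 0.0108% if every order of the 18 libraries were equally likely, but libraries of the same group resemble each other. Genes that fell outnumbered those that rose most among the 7132 least abundant genes (1247 against 233), while among the 7131 genes with mean levels of 1.37 to 7.57 CPM the numbers were 878 and 771. Without Control 1 h replicate 1 the count was 4132 (3802 of the 6776 still called), and without Control 24 h replicate 3 it was 4291. Without composition factors 55.4% of 6121 calls were higher, against 36.6% with TMM.

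**Figure D2:**
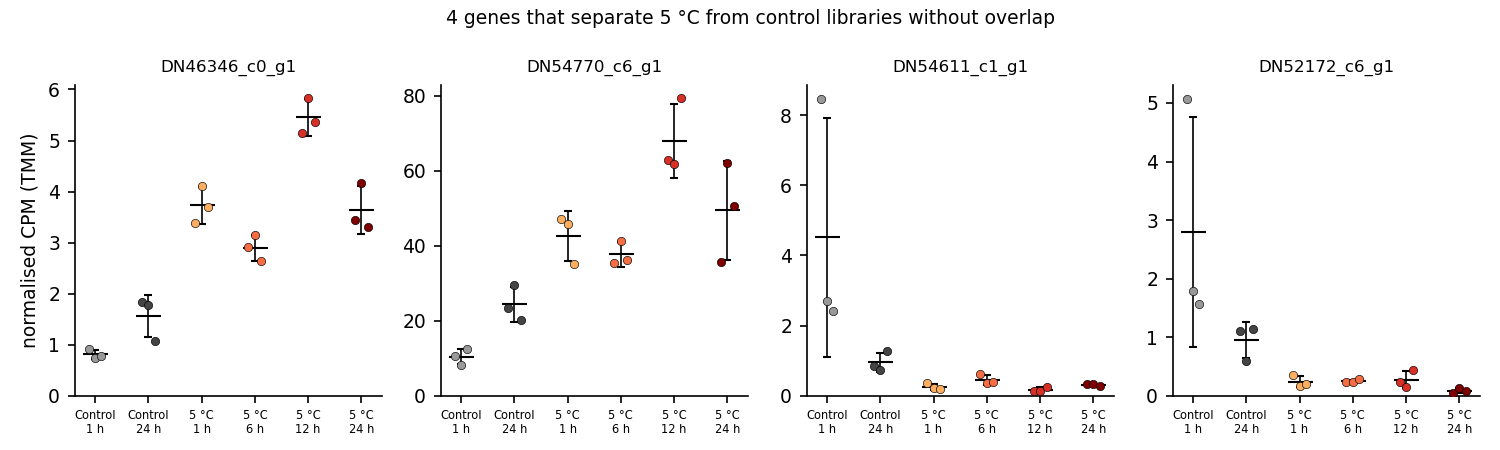
Normalised CPM of the 4 genes named over all times at 5 °C, one panel per gene with its own vertical axis; points are libraries, and horizontal marks with bars are the mean ± SD of 3 libraries. TRINITY_DN46346_c0_g1 and TRINITY_DN54770_c6_g1 are highest at 12 h, with means of 5.45 and 68.0 CPM, and the other 2 genes are highest in Control 1 h.

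At 1 h, TRINITY_DN48885_c0_g1 and TRINITY_DN52710_c1_g2 were higher at 5 °C than in the control of that time, and TRINITY_DN54611_c1_g1 and TRINITY_DN48400_c6_g1 were lower. TRINITY_DN48885_c0_g1 went from 3.69 ± 1.3 to 19.8 ± 0.99 CPM (SD, n = 3 each), a 5.34-fold rise (log2 2.42 ± 0.25 SE, edgeR adjusted p = 0.000323). TRINITY_DN52710_c1_g2 rose 10.3-fold (log2 3.37 ± 0.36 SE, adjusted p = 0.000323). TRINITY_DN54611_c1_g1 went from 4.52 ± 3.4 to 0.253 ± 0.084 CPM, 17.3-fold lower, and TRINITY_DN48400_c6_g1 was 14.5-fold lower, with adjusted p of 0.000657 and 0.000822. Without Control 1 h replicate 1 the log2 change of TRINITY_DN54611_c1_g1 was -3.27 (adjusted p = 0.0011), against -4.11 with it. The same 4 genes passed in each of the 18 fits that left out a library. In Control 24 h, TRINITY_DN48885_c0_g1 stood at 11.8 ± 3.0 CPM and TRINITY_DN52710_c1_g2 at 4.40 ± 1.7 CPM. In all 6668 genes changed, 2547 higher and 4121 lower, with a median absolute log2 change of 1.58. Of the 7131 longest genes 32.4% were called, 783 higher and 1529 lower, and of the 7132 shortest 16.4%, 527 higher and 646 lower. The count was 2300 without Control 1 h replicate 1 (2173 of the 6668 still called) and 3953, 3999 and 3956 without 5 °C 1 h replicate 1, 2 or 3. Against Control 24 h alone it was 1 with all libraries, but 582 without Control 1 h replicate 1, 3 and 29 without Control 24 h replicate 2 or 3, and 0 without 5 °C 1 h replicate 1 or 3 (edgeR; 4209 and 3582 at an unadjusted p under 0.05). Against both controls it was 3120, and 1094, 590 and 759 without 5 °C 1 h replicate 1, 2 or 3; these references were chosen after seeing the data. Without composition factors 60.0% of 6158 calls were higher, against 38.2% with TMM.

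**Figure D3:**
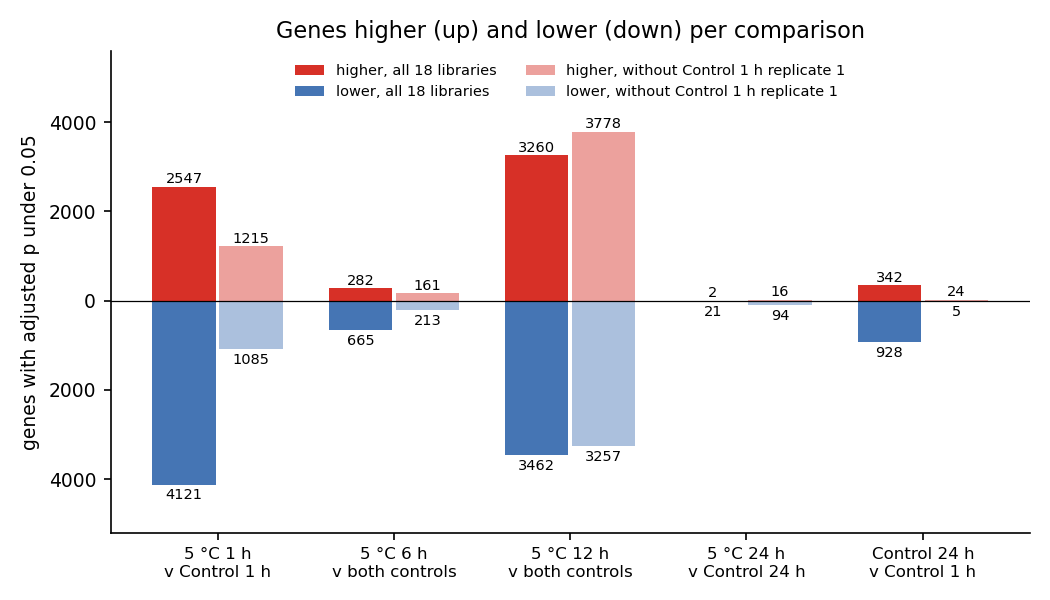
Number of genes with adjusted p under 0.05 in each comparison, higher above 0 and lower below 0, with all 18 libraries (solid) and without Control 1 h replicate 1 (pale). With all libraries 6668 genes are called at 1 h and 23 at 24 h; without that library 2300 and 110.

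At 6 h, for which the series has no control of its own, TRINITY_DN46346_c0_g1 was 2.58-fold higher than the mean of both control groups (log2 1.37 ± 0.20 SE, adjusted p = 0.027). TRINITY_DN51678_c4_g3 had 17 to 46 reads in each 6 h library and 1 read in the 6 control libraries together, a ratio of 141 with a 95% interval of 24.6 to 5622 (adjusted p = 0.0209). It had 8 to 17 reads at 12 h and 3 to 28 at 24 h. TRINITY_DN51753_c4_g3 was 3.10-fold lower (0.898 ± 0.23 CPM at 6 h against 3.54 ± 0.20 and 2.18 ± 0.26 in Control 1 h and 24 h), and TRINITY_DN41855_c0_g1 was 8.28-fold lower (adjusted p of 0.027 for both). In all 947 genes changed, 282 higher and 665 lower; of the 7131 longest genes 64 were higher and 271 lower, and of the 7132 shortest 63 and 78. With each library's mean transcript length deviation as a covariate, chosen after seeing the data, edgeR called 0 at 6 h (1513 at an unadjusted p under 0.05), and with fragment length 217. The count rested on the reference, 7376 against Control 1 h alone and 0 against Control 24 h alone (1328 genes at an unadjusted p under 0.05; against both, DESeq2 called 3373 and limma-voom 129). Against Control 1 h alone it was 1986 without Control 1 h replicate 1 and 3785 and 3843 without 5 °C 6 h replicate 2 or 3. Against Control 24 h alone it was 1 without 5 °C 24 h replicate 2 and 0 in the other fits that left out a library (edgeR; 786 to 2445 at an unadjusted p under 0.05). Against both controls it moved to 0, 1 and 0 without 5 °C 6 h replicate 1, 2 or 3, to 282, 2328 and 2 without Control 24 h replicate 1, 2 or 3, and to 374 and 4708 without Control 1 h replicate 1 or 3. It moved to 250 to 534 without any one of the 5 °C 1 h or 24 h libraries or 12 h replicate 1 or 3. TRINITY_DN46346_c0_g1 lost its call without any one of the 6 h libraries, TRINITY_DN51678_c4_g3 without replicate 1 or 3 of them, and the 2 genes that fell without any one of them or Control 24 h replicate 3. Without composition factors 41.8% of 624 calls were higher, against 29.8% with TMM.

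At 12 h, TRINITY_DN46346_c0_g1 was 4.84-fold and TRINITY_DN53658_c0_g3 3.73-fold higher than the mean of both control groups (log2 2.28 ± 0.19 and 1.90 ± 0.17 SE, edgeR adjusted p = 2.34e-05 for both). TRINITY_DN53658_c0_g3 reached 90.1 ± 9.4 CPM, against 18.5 ± 2.7 in Control 1 h and 31.4 ± 6.4 in Control 24 h (SD, n = 3 each). TRINITY_DN49996_c12_g3 was 3.06-fold lower (adjusted p = 7.94e-05). It stood at 9.13 ± 1.9 CPM at 12 h and 15.2 ± 1.2 at 1 h, and at 31.2 ± 1.6 and 26.7 ± 2.6 at 6 h and 24 h, against 25.6 ± 0.77 in Control 1 h and 30.5 ± 6.3 in Control 24 h. TRINITY_DN54384_c0_g1 had 3 reads in the 12 h libraries together and 25 to 101 in each control library, a ratio of 61.0 with a 95% interval of 20.7 to 297.6 (adjusted p = 6.68e-05). In all 6722 genes changed, 3260 higher and 3462 lower. Of the 7131 longest genes 1130 were higher and 621 lower, and of the 7132 shortest 467 were higher and 761 lower. Among the longest genes this lean was opposite to that at 6 h, while the shortest leaned lower at both times. The count was 7035 without Control 1 h replicate 1, with 5901 of the 6722 still called, and 4028 and 4019 without 5 °C 12 h replicate 1 or 3. In transcript length deviation only Control 1 h replicate 1 among the controls lay as high as the 12 h libraries. With this deviation as a covariate, chosen after seeing the data, the count was 8852, and with fragment length 6215. Against Control 24 h alone it was 3119, and 4997 without Control 1 h replicate 1, 868 and 941 without Control 24 h replicate 1 or 2, and 2038, 1374 and 1803 without 5 °C 12 h replicate 1, 2 or 3. Without composition factors 64.3% of 6260 calls were higher, against 48.5% with TMM.

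At 24 h, TRINITY_DN49464_c0_g1 was 2.57-fold and TRINITY_DN49210_c0_g1 9.58-fold higher than in the control of that time, with an edgeR adjusted p of 0.0442 for both, and these were the 2 genes that rose. TRINITY_DN49464_c0_g1 stood at 29.8 ± 3.9 CPM against 11.6 ± 2.2 in Control 24 h, and at means between 19.4 and 36.8 CPM at the other times at 5 °C (SD, n = 3 each). Of the 21 genes that fell, TRINITY_DN49537_c1_g1 went from 1.10 ± 0.28 to 0.0787 ± 0.070 CPM, and TRINITY_DN52323_c1_g1 from 15 to 24 reads per library to 1 read in all, a ratio of 57.3 with a 95% interval of 9.86 to 2303 (adjusted p of 0.031 for both). Of the 23 calls 10 lay among the 7132 least abundant genes, and 2470 genes had an unadjusted p under 0.05. The number was 110 without Control 1 h replicate 1 (all 23 still called). It was 0 without Control 1 h replicate 2, Control 24 h replicate 1 or 3, 5 °C 1 h replicate 1 or 3, 6 h replicate 3, 12 h replicate 1 or any one of the 24 h libraries. It was 5 to 14 without 5 °C 1 h replicate 2, 6 h replicate 1 or 2 or 12 h replicate 3. It was 0 by limma-voom (2186 at an unadjusted p under 0.05), 171 by DESeq2, and 6 with DESeq2's size factors. Fragments were 175 to 181 bases long at 5 °C 24 h and 161 to 168 in Control 24 h. These lengths do not overlap, so fragment length and 5 °C cannot be told apart here. With fragment length as a covariate the number was 0 (edgeR, 1735 at an unadjusted p under 0.05), and with the transcript length deviation 149. Against both controls, a reference chosen after seeing the data, it was 1637, and 2968 without Control 1 h replicate 3, 1033 without Control 24 h replicate 3, and 793 and 403 without 5 °C 24 h replicate 1 or 3. Every named gene lost its call in at least 10 of the 18 fits that left out a library.

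Between the control groups, TRINITY_DN19611_c0_g1 had no reads in Control 1 h and 70 to 139 per library in Control 24 h, at least 73.7-fold higher (edgeR adjusted p = 0.00387), and 0 to 53 reads at 5 °C. TRINITY_DN49657_c0_g3 was higher in Control 24 h by a log2 change of 4.32 ± 0.53 (SE; 2.79 ± 1.1 against 0.140 ± 0.12 CPM, SD, n = 3 each) and at means of 1.73 to 2.98 CPM at 5 °C. TRINITY_DN43916_c0_g1 and TRINITY_DN48282_c0_g1 were 14.3-fold and 13.2-fold lower in Control 24 h (adjusted p = 0.00494 for both). In all 1270 genes changed, 342 higher and 928 lower, with 385 of those that fell among the 7131 longest genes. With the transcript length deviation as a covariate 1 gene was called, and with fragment length 43. These are differences between libraries labelled as the 2 control groups, and the labels and pools could not be checked from the files. A grouping that exchanged Control 24 h replicate 3 with Control 1 h replicate 3 called 5239 genes. A fit of the control libraries alone called 0 by edgeR (3468 at an unadjusted p under 0.05), and with all libraries DESeq2 called 3546 and limma-voom 176. The count was 29 without Control 1 h replicate 1, 5449 without replicate 3, 7, 4 and 3912 without Control 24 h replicate 1, 2 or 3, and 215 to 701 without any one library at 5 °C. TRINITY_DN43916_c0_g1 and TRINITY_DN48282_c0_g1 lost their calls without Control 24 h replicate 1 or 2. Their log2 changes of -3.84 and -3.72 were -2.96 and -2.74 without Control 1 h replicate 1 (adjusted p of 0.0107 and 0.0102), and the first was -4.43 without Control 24 h replicate 3. Without composition factors 49.3% of 383 calls were higher, against 26.9% with TMM. Control 24 h replicate 3 correlated more closely with Control 1 h replicate 2 (Pearson r = 0.967 across genes) than with the other 2 Control 24 h libraries (0.954 and 0.940).

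No gene passed the edgeR test for a difference between the 5 °C effect at 24 h and that at 1 h. In edgeR 5618 genes had an unadjusted p under 0.05, and limma-voom also called 0. DESeq2 called 1254, but it gave no adjusted p for 12905 of the 28525 genes and so adjusted over fewer. The nearest in edgeR were TRINITY_DN52710_c1_g2, with a log2 difference of -3.10 ± 0.47 (SE), and TRINITY_DN41015_c0_g1 (adjusted p = 0.112 for both differences), values that did not pass. TRINITY_DN41015_c0_g1 had 0 reads in Control 24 h and 7 to 10 per library at 5 °C 24 h, and 5 to 13 in Control 1 h and 1 to 4 at 5 °C 1 h. The count was 1234 without Control 1 h replicate 3, 14 without Control 24 h replicate 3, 7 with fragment length as a covariate and 1 with the transcript length deviation. Across the 6668 genes called at 1 h, fold changes at 24 h, from other libraries, had the same sign in 70.1% and a Pearson r of 0.528 across genes, which are not independent replicates. Over the same list this r was 0.276 without Control 24 h replicate 3. Over all genes tested r was 0.337 (simulated with no effect, -0.00416), but 0.197 without Control 1 h replicate 1, 0.0360 without Control 24 h replicate 3 and 0.00324 without both, settings chosen after seeing the data. The genes that rose at 1 h had a median log2 change of 0.18 at 24 h, and those that fell of -0.18.

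Fold changes at 1 h also went with those at 6 h (r = 0.700 over all genes, covariance 0.738) and at 12 h (r = 0.619, covariance 0.851). These comparisons share the Control 1 h libraries, and sharing alone gave r of 0.317 and 0.299 and covariances of 0.0799 and 0.0765 in simulated groups with no effect. The simulation used a single spread per gene for all groups. The biological coefficient of variation was 0.482 in Control 1 h, against 0.338 in common, so these simulated values may be too low. Of the genes higher at 1 h 1578 were also higher at 12 h, and of those lower 1644 also lower, where independent lists would share 291 and 500.2. Lists of the same sizes, ranked by p in the same simulation with no effect, shared 747 and 910, which may be too low for the same reason. The first pair of numbers leaves out the shared controls and the second the effects, so part of the excess over either may come from the shared controls. With Control 24 h as the only reference at 6 h and 12 h no libraries were shared, and r with the 1 h changes was 0.392 and 0.310. These values rested on control libraries: they were 0.0325 and 0.0982 without Control 24 h replicate 3, 0.253 and 0.314 without Control 1 h replicate 1, and -0.0104 and 0.141 without both. With this reference 446 genes were higher at both 1 h and 12 h and 516 lower. Independent lists would share 119 and 258.0, and lists of the same sizes in simulated groups with no effect shared 144 and 280. The 12 h count with this reference itself ran from 868 (without Control 24 h replicate 1) to 4997 (without Control 1 h replicate 1).

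Among the 4 times at 5 °C, 3106 genes differed, and TRINITY_DN49996_c12_g3, above, shows the usual shape. In 87.2% of these genes the means at 1 h and 12 h lay both above (1273 genes) or both below (1436 genes) those at 6 h and 24 h. This share was 59.2% over all genes tested and would be 33.3% if every order of the 4 times were equally likely. By pairs of times, edgeR called 4379 genes between 12 h and 6 h (2197 higher at 12 h), 2619 between 24 h and 12 h, 169 between 24 h and 1 h, 121 between 6 h and 1 h and 6 between 12 h and 1 h. Between 24 h and 6 h it called 0, with 1547 genes at an unadjusted p under 0.05, 0 by limma-voom and 9 by DESeq2. The libraries also differed along this line in the length of the transcripts: the mean log2 deviation of the deposited lengths was 0.0471 to 0.0544 in the 12 h libraries, -0.00161 to 0.0286 at 1 h, -0.0233 to -0.0121 at 24 h and -0.0467 to -0.0399 at 6 h. Controls covered a similar range, from -0.0525 (Control 24 h replicate 2) to 0.0544 (Control 1 h replicate 1). The highest controls after that library were Control 1 h replicate 2 (0.0280) and Control 24 h replicate 3 (0.00930). Fragments were 175 to 181 bases long at 24 h, longer than in every other library (159 to 174). With the transcript length deviation as a covariate 18 of the 28525 genes tested differed over the 4 times, and with fragment length 830, covariates chosen after seeing the data. With these 2 covariates in turn edgeR called 0 (6590 at an unadjusted p under 0.05) and 2853 between 12 h and 6 h, 1253 and 0 (3445 unadjusted) between 24 h and 12 h, 706 and 8 between 24 h and 1 h, 2 and 2 between 6 h and 1 h, and 8 and 3 between 12 h and 1 h. The count over the 4 times was 5383 without Control 1 h replicate 1, 1440 without 5 °C 12 h replicate 2, and 1854, 1646 and 1738 without 5 °C 6 h replicate 1, 2 or 3 and 2068 without 24 h replicate 3. Control libraries enter these tests between times only through the shared spread, the filter and the scaling.

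**Figure D4:**
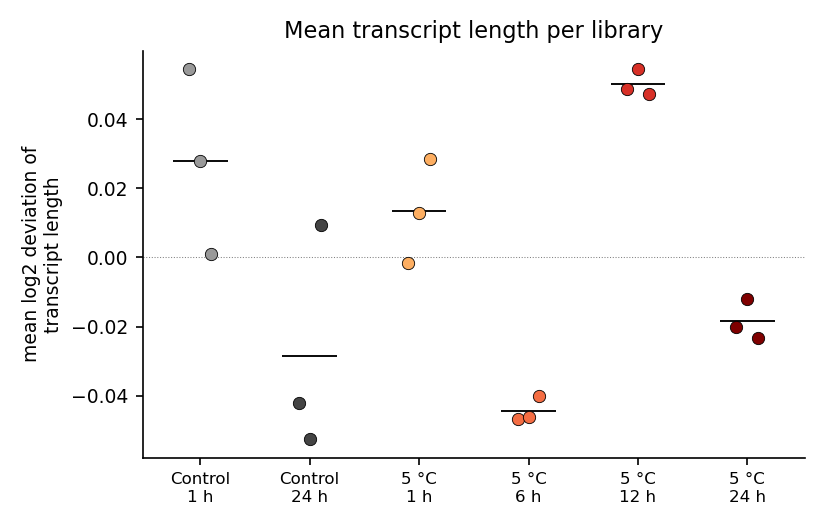
Mean log2 deviation, per library, of the deposited transcript length from each gene's mean over libraries, in 7740 genes; points are libraries and lines are group means of 3. The 6 libraries of 5 °C 1 h and 12 h lie between -0.00161 and 0.0544, all above the 6 libraries of 5 °C 6 h and 24 h.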

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

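The tests over the 4 times at 5 °C and the counts over other splits of the libraries were planned; the tests of deposited length, of genes found almost entirely in 1 library and of each explanation were chosen after the results were seen.

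Levels at 5 °C were compared between times, which leaves out the controls. This equals a difference between effects of 5 °C only with the same control reference, as at 6 h and 12 h. For 24 h and 1 h, each against its own control, that difference passed in 0 genes (edgeR, 5618 at an unadjusted p under 0.05). Levels differed in 4379 genes for 12 h against 6 h and 2619 for 24 h against 12 h (edgeR). They differed in 169 for 24 h against 1 h, 121 for 6 h against 1 h and 6 for 12 h against 1 h. The first count was 1983, 1746 and 1976 without 5 °C 6 h replicate 1, 2 or 3 and 2061 without 12 h replicate 2. The second was 4153 without Control 1 h replicate 1, 1042 and 1518 without 5 °C 12 h replicate 2 or 3, and 708 and 823 without 24 h replicate 1 or 3. The smaller counts moved by over 1.5 times in 13, 15 and 7 of 18 fits that left out a library: between 0 (5 °C 24 h replicate 3) and 801 (Control 1 h replicate 1), between 0 (5 °C 1 h replicate 1 or any one of the 6 h libraries) and 1275 (Control 1 h replicate 1), and between 2 (5 °C 1 h replicate 3 or 12 h replicate 2) and 281 (12 h replicate 3).

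In most genes that differed over the 4 times, the means at 1 h and 12 h lay on one side of those at 6 h and 24 h. By test the differences lay mainly with 12 h, as 1 h differed from 6 h in 121 genes and from 24 h in 169. The explanations were tested on pairs with 12 h. A bias by transcript length was argued against as the whole cause for 12 h against 6 h. After a smooth length trend was removed from each library, 4160 genes differed between 12 h and 6 h. Fragment length was argued against for this pair as well, as the lengths overlapped and 2853 genes differed with it as a covariate. Between 24 h and 12 h the fragment lengths did not overlap, and edgeR called 0 genes with this covariate (3445 at an unadjusted p under 0.05), so time and fragment length cannot be told apart there. With each library's mean transcript length deviation as a covariate edgeR called 0 genes between 12 h and 6 h (6590 at an unadjusted p under 0.05); the libraries at 1 h and 12 h all lay above those at 6 h and 24 h in this measure, so a property of the libraries that it tracks and time cannot be told apart. An effect of time itself stays open.

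The 3 against 3 comparisons have 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 4379 and 0 for 12 h against 6 h, 2619 and 1 for 24 h against 12 h, 169 and 0 for 24 h against 1 h, 121 and 1 for 6 h against 1 h, 6 and 0 for 12 h against 1 h, and 0 and 0 for 24 h against 6 h, where all 10 splits gave 0. For the test over the 4 times, 1 of 100 splits, the real one, gave 3106 genes and the highest other gave 1627. The splits break up the libraries of a time, so they do not tell time from another property that these libraries share.

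The deposited transcript length, which the main comparisons of levels do not use, shifted in 781 of 7740 genes at 12 h against both controls, 618 longer and 163 shorter, and in 1788 at 12 h against 6 h (limma, adjusted p under 0.05), while 0 shifted between the control groups (1476 at an unadjusted p under 0.05). Of 100 splits 2 gave as many as 781, the real one and another with 895. That other split put Control 1 h replicate 1 with 5 °C 12 h replicates 1 and 2. Few random draws of single libraries gave as many, but a count of this size did not need the real 12 h group. The splits of 12 h and 6 h numbered 10, too few for a share under 0.05, with 1 as the highest other. Between the control groups a split that put Control 24 h replicate 3 with Control 1 h replicates 1 and 2 gave 960, which points to a structure of the control libraries. The first count was 324, 354 and 417 without 5 °C 12 h replicate 1, 2 or 3, 1245 without Control 1 h replicate 1, and 457, 453 and 1282 without Control 24 h replicate 1, 2 or 3. The count between control groups was 770 without Control 24 h replicate 3, 611 without Control 1 h replicate 3, and 1 without 5 °C 1 h replicate 1 or 12 h replicate 3. The second count was 1146 without 5 °C 6 h replicate 2 and 1167 without 5 °C 12 h replicate 2.

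Some genes had 50 or more reads in 1 library and a share of its reads over 50 times that in any other library, limits set after the data were seen. In 5 °C 12 h replicate 2 there were 236 such genes with 4.86% of the reads; 77 of them were among the genes tested, and all 77 were called at 12 h. In 5 °C 1 h replicate 3 there were 2 such genes with 2.19% of the reads, in 5 °C 1 h replicate 1 there were 8 with 0.00643%, and in 5 °C 6 h replicate 1 there were 6 with 0.00237%. No control library had more than 1.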

How the results depend on the processing

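Other references at 1 h and 24 h, sample weights, covariates, the length trend, following all genes, correlations over all genes or a fixed list with libraries left out, the tests of shifted lengths, and leaving out the most abundant gene or a pair of libraries were chosen after seeing the data; the other settings were planned. Counts are of genes with an adjusted p under 0.05. Where a count moved by over 1.5 times the cause was not tested, also where fewer genes or libraries entered the fit. A library outside the groups compared enters a test only through the shared spread, the filter and the scaling. The whole-profile difference stayed past its threshold in all settings (exact permutation p from 0.000242 to 0.00659), with pseudo-F from 2.61 to 4.30 when 1 library was left out. Leaving out 1 library gave 2300 to 8808 at 1 h, 0 to 4708 at 6 h, 4019 to 7400 at 12 h, 0 to 110 at 24 h, 4 to 5449 between controls, 0 to 1234 for the difference between 24 h and 1 h, 1440 to 5383 over the 4 times at 5 °C and 4132 to 8935 over all times. It gave 324 to 1282 shifted lengths at 12 h, 0 to 770 between controls and 1146 to 1962 at 12 h against 6 h, and a follow-up r, over genes called anew in each fit, of 0.305 to 0.715 (0.276 to 0.604 over the list called with all libraries). With all libraries r was 0.337 over all genes tested and 0.854 for the 100 genes with the smallest p. DESeq2 called 3373 at 6 h, 171 at 24 h, 3546 between controls and 5019 over the 4 times. It called 1254 for the difference, with 12905 genes left without an adjusted p, against 217 in each of those comparisons. Its size factors in edgeR gave 6 at 24 h. limma-voom called 129 at 6 h, 0 at 24 h (2186 at an unadjusted p under 0.05) and 176 between controls; with sample weights it called 7192, 68 and 7009, with 1964 for the difference and 7896 over the 4 times. edgeR with legacy=FALSE called 1642 at 6 h and 2063 between controls. No composition factors gave 624 at 6 h, 41 at 24 h and 383 between controls. No filter gave 2243 at 6 h, 902 at 24 h, 2082 between controls, 1217 for the difference and 5250 over the 4 times. A stricter filter, which tests fewer genes, gave 4174 at 1 h, 125 at 6 h, 4076 at 12 h, 0 at 24 h (605 unadjusted) and 4059 over all times. A fold over 2 as well left 1934 over the 4 times and 3120 over all times. Fits of only the groups compared used fewer libraries and estimated the spread from those alone. At 1 h, 6 h and 12 h they gave 1774, 0 (5798 unadjusted) and 2798. At 24 h they gave 1, and between controls 0 (3468 unadjusted). Against both controls there were 3120 at 1 h and 1637 at 24 h, against Control 1 h alone 7376 at 6 h, and against Control 24 h alone 1 at 1 h, 0 at 6 h (1328 unadjusted) and 3119 at 12 h. In this order these counts ran from 590 to 4598, 403 to 2968, 1986 to 10742, 0 to 582, 0 to 1 and 868 to 4997 when 1 library was left out, and were 2754, 1424, 1986, 582, 0 (2142 unadjusted) and 4997 without Control 1 h replicate 1. Fragment length as a covariate gave 217 at 6 h, 0 at 24 h (1735 unadjusted), 43 between controls, 7 for the difference and 830 over the 4 times. At 24 h the fragment lengths at 5 °C and in Control 24 h did not overlap, so this covariate cannot tell 5 °C from fragment length there. The transcript length deviation as a covariate gave 0 at 6 h (1513 unadjusted), 149 at 24 h, 1 between controls, 1 for the difference and 18 over the 4 times. It gave 5319 at 1 h, 8852 at 12 h and 8602 over all times. Removing the length trend gave 1 for the difference, and a minimum of 50 reads gave 5 shifted lengths between controls. Without Control 1 h replicate 1 and Control 24 h replicate 3 there were 3195 at 1 h, 151 at 6 h, 0 at 24 h (3753 unadjusted), 383 for the difference, 6642 over the 4 times and 3405 over all times, and the all-gene r of the 1 h changes with those at 6 h against Control 24 h turned from 0.392 to -0.0104.

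With the replicate number as a block, 285 genes differed between controls, and no other count of a comparison moved by over 1.5 times apart from those of pairs of times. The numbers did not pair the libraries: over 45 pairs with the same number the mean correlation of deviations was 0.0035, from -0.547 to 0.286, and 4 of 18 libraries correlated best with their own number.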

Other observations

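The splits of the libraries were planned, and the tests of explanations were chosen after the results were seen.

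TRINITY_DN51678_c4_g3, called at 6 h, had at most 1 read in any library at 5 °C 1 h, while its means at 6 h, 12 h and 24 h were 0.877 ± 0.30, 0.440 ± 0.17 and 0.593 ± 0.42 CPM (SD, n = 3 each). TRINITY_DN41855_c0_g1, also called at 6 h, had means of 0.205 to 0.511 CPM at all 4 times at 5 °C, against 2.94 ± 1.3 in Control 1 h and 1.05 ± 0.41 in Control 24 h. TRINITY_DN43916_c0_g1 and TRINITY_DN48282_c0_g1, lower in Control 24 h than in Control 1 h, stood at 1.20 ± 0.27 and 1.13 ± 0.15 CPM at 5 °C 1 h, and at means of 0.194 to 0.254 and 0.327 to 0.419 CPM at the later times. In the edgeR test over the 4 times at 5 °C the adjusted p was 0.00867 for TRINITY_DN51678_c4_g3, 0.278 for TRINITY_DN41855_c0_g1, 0.00673 for TRINITY_DN43916_c0_g1 and 0.0486 for TRINITY_DN48282_c0_g1, values not repeated with libraries left out. Of the 3106 genes that differed over the 4 times at 5 °C, 1226 had their highest mean at 12 h, 1030 at 6 h, 496 at 24 h and 354 at 1 h. The lowest mean was at 12 h in 1395, at 6 h in 867, at 24 h in 621 and at 1 h in 223. The spread within groups, as a biological coefficient of variation, ran from 0.164 at 5 °C 6 h to 0.482 in Control 1 h. The 6 groups differed as whole profiles (pseudo-F 2.69, permutation p = 1e-05, the smallest the permutations can give), with 52.8% of the squared distances between groups.

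Control 1 h replicate 1 stood apart: 3549 genes were at least 4-fold higher and 1604 at least 4-fold lower there than in the median library. RNA of another organism would add transcripts and lower the animal's own by one factor; the distance from the median to the 10th percentile of its log2 deviations was 1.53, against 0.950 in the highest other library, which argues against that as the whole cause. A loss of reads by length was argued against by a count of 6610 genes at 1 h with the length trend removed, against 2300 without this library. Without the most abundant gene the count was 6613. TMM factors already adjust for a gene that takes a large share, so this count could hardly move and does not decide on that share. No biological explanation was tested, and a difference between the animals of this pool stays open.

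Fold changes at 1 h and 24 h, which share no library, went together. Over all genes tested r fell from 0.337 to 0.00324 without Control 1 h replicate 1 and Control 24 h replicate 3 (0.197 without the first alone, 0.0360 without the second alone), so a joint deviation of these 2 control libraries may account for that relation. For the 6668 genes called at 1 h with all libraries r fell from 0.528 to 0.281 without both (0.276 without Control 24 h replicate 3 alone), just above the bound of 0.264 for this explanation. The requirement that r lie beyond the bound by more than its SD over fits that left out 1 library (0.0652) was added after this value was seen; without it 0.281 would argue against these libraries as the whole cause, and with it that stays open. For the 3195 genes called without both libraries r was 0.516 in that fit and 0.673 with all libraries, and a lasting effect of 5 °C also stays open.

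The counts at 12 h (real 6722, highest of 99 others 6057) and over all times (6776 and 2540) were each reached by 1 of 100 splits, the real one. Random draws of single libraries thus seldom gave as many. The splits break up the libraries of a group, so they do not tell 5 °C from another property that these libraries share. The split with 6057 kept the 12 h libraries together and reshuffled the controls. At 6 h 5 of 100 splits gave 947 or more, so chance is not excluded; the highest, 10163, put Control 1 h replicates 1 and 2 with Control 24 h replicate 3, which points to a structure of the control libraries. For the difference between 24 h and 1 h all 100 splits reached the real count of 0 (edgeR; 5618 genes at an unadjusted p under 0.05, limma-voom 0, DESeq2 1254), and the highest was 2359, a split that kept the Control 1 h libraries together under another label and points to a structure of the libraries. For 1 h, 24 h and the control groups there are 10 splits, too few for a share under 0.05: the real counts and the highest others were 6668 and 0, 23 and 0, and 1270 and 5239. The split with 5239 again put Control 1 h replicates 1 and 2 with Control 24 h replicate 3, and 2 of the 10 splits gave 1270 or more.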
